A study of Homo sapiens with 20 samples.

How the data were processed

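Messenger RNA was measured in human primary T cells purified from peripheral blood mononuclear cells, in 20 libraries that fall into 4 groups of 5. CD4 or CD8 T cells had been electroporated with an siRNA against FOXP3 (siFOXP3) or with a non-specific control siRNA of medium GC content (siNS), and RNA was taken on day 4 after electroporation. Per the labels' protocols, at least 75 ng of total RNA with a quality number above 8 went into a stranded poly(A) library kit. Groups and replicate numbers were taken from the sample titles. For 1 library, CD4 siFOXP3 replicate 5, the title and source name say CD4 while a subtype label says CD8; it was kept in the CD4 group. Its values are those of CD4 T cells and argue against the subtype label. It had at least 327 CPM of CD4 and at most 1.22 CPM of CD8A (CPM is defined below). CD8 siNS libraries had at least 387 CPM of CD8A. Nothing in the labels says whether the replicates of a group came from separate donors, so p-values measure the spread between these libraries.

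The authors deposited a table of expected counts, which are estimated counts of fragments per gene that need not be whole, and a table of FPKM (fragment counts scaled by transcript length and library size), each with 28456 gene symbols and 20 columns. Per the submitters' processing notes, STAR 2.4.2a, RSEM 1.2.22 and the genome build hg19 were used; their roles, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be told apart with certainty, and genes of near-identical families share fragments by RSEM's estimate. No coordinates are given because an annotation of hg19 was not used here. All columns of both tables were used.

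The deposited expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 14942, and libraries were scaled with TMM. One quasi-likelihood model (glmQLFit with the robust option, glmQLFTest) held the 4 groups without a block. It gave siFOXP3 against siNS in CD4 and in CD8 T cells, the interaction of siRNA and subset, and CD4 against CD8 under siNS. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled counts relative to library size, computed from the deposited estimated counts. Levels of XIST, TSIX and Y-linked genes were left out of every table, and genes with common germline deletions were not named.

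The replicate numbers were checked as a pairing. Deviations of log2 CPM from the group means were correlated between same-numbered libraries, and numbers were taken to pair the libraries where all 5 correlations exceeded 0.1. Within CD4 the 5 correlations ran from 0.509 to 0.827, and each siFOXP3 library correlated best with the siNS library of its own number. The pairing thus comes from the data, not from the labels. For CD4, a fit of the 10 CD4 libraries with the replicate number as a block is therefore given beside the unblocked result; it tested 14020 genes and was added after the check.

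A total of 37 gene lists with 795 entries were fixed before the data were examined, covering T cell function, cell death, stress, siRNA side effects and markers of other cell types. Of the entries, 774 had a row in the table, 31 of them under an older symbol, and 727 were tested; the others are not analysed here. Lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over all lists within a comparison. FOXP3 itself was also compared with an exact permutation test of log2 CPM.

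The rule for named genes was also fixed beforehand. For each subset it took FOXP3 and the 8 higher and 8 lower genes with the largest change among those called, with a mean of at least 1 CPM over all libraries and the same sign in at least 4 of 5 same-numbered pairs. Places left empty were filled from the blocked fit where the numbers pair the libraries. It added up to 4 members with the smallest unadjusted p from each list described. For CD4 against CD8 it took CD4, CD8A and CD8B and 5 genes in each direction. Variable segments of antigen receptors, classical HLA genes outside the lists and features without a gene symbol were never named. Some genes that the rule takes are not reported here. SPTY2D1 and CTLA4 in CD8 T cells were named after their values were seen.

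Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the block over all 20 libraries, a fit of only the groups compared, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, and each library left out in turn. Added after seeing the data were the block within CD4 with its own alternatives, and surrogate variables from sva 3.50.0 (3 in CD4 and 3 in CD8). Replicate libraries were compared for duplicates by the chi-square per gene of each pair; the lowest value over all pairs was 18.8, far above sampling noise, so each library counts once.

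The fits were tested on simulated counts with the real means, library sizes and dispersions, in which 200 genes were changed in CD4. Without a block (14744 genes), 0 of 50 genes changed by 1.25-fold, 10 of 50 changed by 1.5-fold, 29 of 50 changed by 2-fold and 47 of 50 changed by 4-fold were recovered, with 5 false calls. With the block within CD4 (13838 genes), the corresponding numbers were 26, 44, 49 and 50 of 50, with 10 false calls. The simulated counts without a block were drawn independently for each library, without the pairing found in CD4. Their recovery may therefore overstate what the unblocked fit detects in the real counts, where FOXP3 itself was not called.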

Results

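RNA sequencing was performed on CD4 and CD8 T cells 4 days after electroporation with siRNA against FOXP3, the transcription factor that defines regulatory T cells and is also induced in activated conventional T cells, or with control siRNA. Each of the 4 groups held 5 libraries. Total estimated counts per library ran from 22602220 to 26510383 in CD4 siNS, from 23587038 to 29544535 in CD4 siFOXP3, from 29290655 to 40769229 in CD8 siNS and from 30026961 to 37756230 in CD8 siFOXP3. The study's title places FOXP3 in the context of cell death on restimulation of conventional T cells. The comparisons ask what changes when FOXP3 is reduced in each subset.

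FOXP3, the target, was lower with its siRNA in both subsets. In CD4 T cells it averaged 28.6 ± 7.21 CPM with siFOXP3 and 85.0 ± 21.8 CPM with siNS (SD, n = 5 each), a log2 fold change of -1.57 ± 0.317 (SE). The ranges did not overlap (18.9 to 36.2 against 62.2 to 108 CPM), and the exact two-sided permutation p was 0.00794, the smallest that 5 against 5 libraries allow. That test exchanges libraries freely and leaves the pairing found in CD4 aside. Over all genes without a block the edgeR adjusted p was 0.599, and with same-numbered CD4 libraries paired in a block it was 5.79e-05 at a log2 fold change of -1.58 ± 0.101. In CD8 T cells FOXP3 averaged 24.2 ± 12.1 CPM with siFOXP3 and 59.9 ± 19.6 CPM with siNS (SD, n = 5 each), a log2 fold change of -1.31 ± 0.315, with overlapping ranges of 8.96 to 42.0 and 35.2 to 78.7 CPM. The exact permutation p was 0.0159, and the edgeR adjusted p over all genes was 1.

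**Figure D1:**
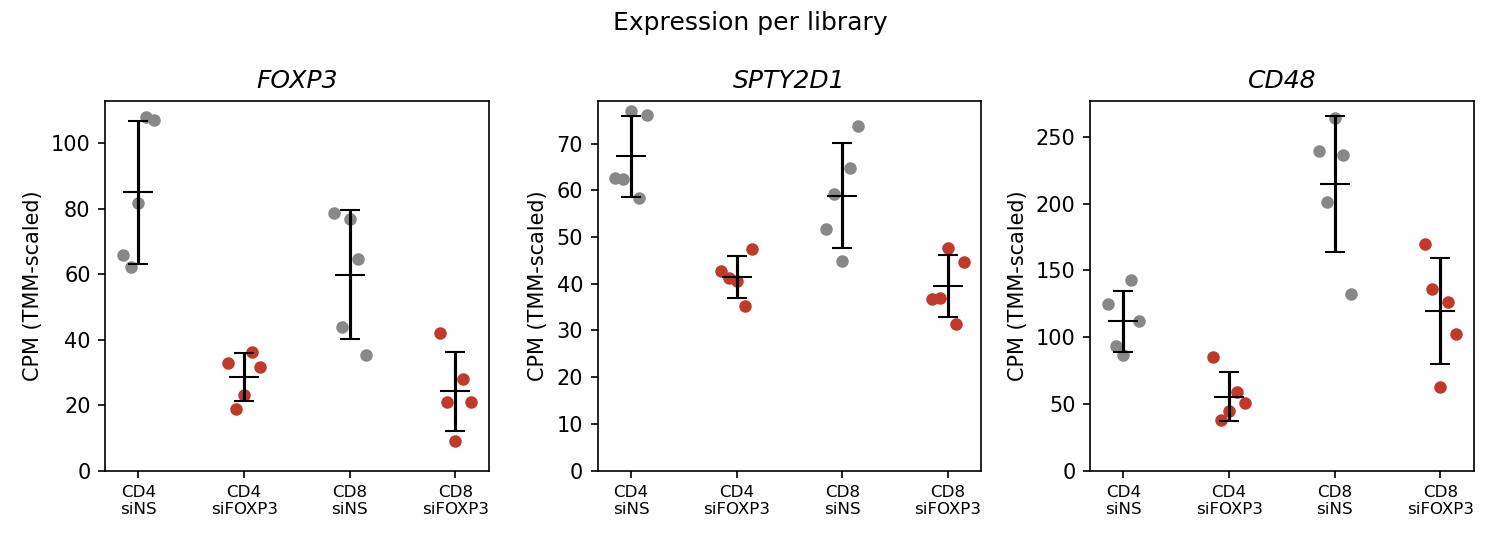
TMM-scaled CPM (vertical axis, from 0) of FOXP3, SPTY2D1 and CD48 in each of the 4 groups; points are libraries (n = 5 per group), bars the mean ± SD, grey siNS and red siFOXP3. In CD4 T cells the siFOXP3 libraries lie below all siNS libraries for each of the 3 genes, while in CD8 T cells the ranges overlap.

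In CD4 T cells, paired by replicate number, FOXP3 siRNA lowered CD48, SPTY2D1, CTLA4 and the interleukin-1 receptors IL1R1 and IL1R2, and raised the cytokine genes IL13 and IL22. CD48, a surface ligand of the SLAM family, averaged 55.3 ± 18.3 CPM with siFOXP3 and 112 ± 22.9 CPM with siNS (SD, n = 5), a 2.07-fold decrease (log2 fold change -1.05 ± 0.096, edgeR adjusted p = 0.000687). SPTY2D1, which encodes a histone chaperone, was 1.62-fold lower (-0.70 ± 0.063, adjusted p = 0.000177). CTLA4, the inhibitory receptor, was 1.51-fold lower (-0.60 ± 0.055, adjusted p = 0.000177). IL1R1 was 1.61-fold lower and IL1R2, the decoy receptor, 1.82-fold lower. NT5E, which encodes the ectonucleotidase CD73, was 1.77-fold lower, and NPTX1 and the protease inhibitor gene SERPINA1 were lower by 1.47-fold and 1.43-fold. IL13 was 1.36-fold higher (0.44 ± 0.060, adjusted p = 0.00522) and IL22 1.45-fold higher (0.53 ± 0.083, adjusted p = 0.0158). UBD, which encodes a ubiquitin-like protein, was 1.48-fold higher, and RAB9A 1.26-fold. The nuclear long noncoding RNAs NEAT1 and MALAT1 were 1.37-fold and 1.27-fold higher. GOLGA8A (1.39-fold higher) belongs to a family of near-identical copies and C7orf55-LUC7L2 (1.32-fold higher) is a readthrough transcript that overlaps other genes, so both values are uncertain. All 16 genes moved in the same direction in 5 of 5 same-numbered pairs. The rule took these genes by their call in the paired fit and by their signs in these same pairs. Their shared direction is therefore no independent check of the calls.

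**Figure D2:**
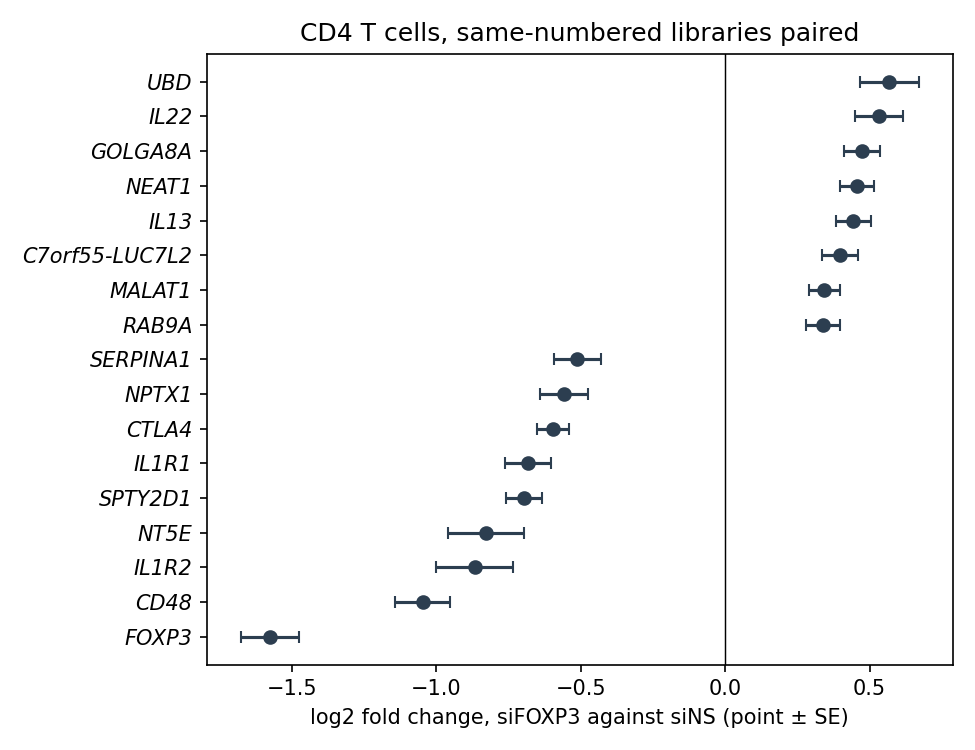
Log2 fold change of siFOXP3 against siNS in CD4 T cells (horizontal axis) for FOXP3 and the 16 genes named by the rule, from the edgeR fit with same-numbered libraries paired; points are estimates and bars ± SE (5 pairs). The values run from -1.58 for FOXP3 to 0.57 for UBD.

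Most of these calls were made only with the pairing. With the replicate block within CD4, edgeR called 9 genes higher and 15 lower of 14020 tested, whereas without a block it called 0 higher and 0 lower of 14942. At an unadjusted p under 0.05 the unblocked fit had 23 higher and 18 lower genes, fewer than chance alone gives on average, and DESeq2 without a block called 2 lower genes, FOXP3 and SPTY2D1. Surrogate variables in place of the block, added after the data were seen, gave 5 lower and 0 higher: FOXP3 (edgeR adjusted p = 0.000205), SPTY2D1 (0.00375), CD48 (0.00441), CTLA4 (0.012) and 1 feature without a gene symbol. Leaving out 1 pair at a time, the blocked counts ran from 4 to 14 higher and from 7 to 26 lower. FOXP3, SPTY2D1, CTLA4, IL1R1, IL13, GOLGA8A and NEAT1 were called whichever of the 5 pairs was left out. RAB9A was called in 0 of those 5 fits, UBD, SERPINA1, TNFRSF1B and C7orf55-LUC7L2 in 1, IL1R2 and NT5E in 2, IL22 and MALAT1 in 3, and CD48 and NPTX1 in 4.

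Among the 29 tested members of the Treg signature list, 4 fell and 0 rose over all genes tested in the paired CD4 fit, and 6 fell and 1 rose when adjusted over the list alone. CTLA4, IL1R1, IL1R2 and TNFRSF1B were the 4; TNFRSF1B, the second tumour necrosis factor receptor, had a log2 fold change of -0.32 ± 0.057 (edgeR adjusted p = 0.0462). The list as a set was shifted lower by camera (adjusted p = 9.67e-10 at the preset correlation). With an estimated correlation the adjusted p = 0.109. Its median log2 fold change was -0.08.

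The list of genes repressed by FOXP3 in regulatory T cells had 17 tested members, of which IL13 and IL22 rose and 0 fell over all genes. Adjusted over the list alone, 4 rose and 1 fell. IL4 had a log2 fold change of 0.46 ± 0.144 and IL17A of -0.43 ± 0.136, neither past the threshold over all genes (adjusted p = 0.39 and 0.415 by edgeR). The set passed in the higher direction at the preset correlation (camera adjusted p = 0.00666), and with an estimated correlation the adjusted p = 0.139. Yet 9 members lay above 0 and 8 below, at a median log2 fold change of 0.04, so most of the list did not move together. Without the block its camera adjusted p was 0.861 at the preset correlation.

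Of 14 SLAM receptors and adaptors, CD48 fell and 0 rose over all genes, and 2 fell adjusted over the list alone. INPP5D, which encodes the lipid phosphatase SHIP1, was 1.15-fold lower (edgeR adjusted p = 0.309 over all genes). The list's camera adjusted p was 0.000482 in the lower direction, and with an estimated correlation the adjusted p = 0.109. Its median log2 fold change was -0.05 and 5 members lay above 0, while CD48 was at -1.05. CD48 may thus carry much of the shift, and the list was not tested without it. Of 15 inhibitory receptors, CTLA4 fell over all genes and 2 fell adjusted over the list alone; HAVCR2 was 1.15-fold lower (adjusted p = 0.26). The camera adjusted p was 0.00028, and the adjusted p = 0.109 with an estimated correlation. CTLA4 is also a member of the Treg signature and CD4 T cell marker lists, so the shifts of these lists are not independent.

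The death receptor and pro-apoptotic BCL2 family lists did not pass as groups, and the p53 targets passed only at the preset correlation. In CD4 T cells 0 of 27 death receptor pathway genes were called over all genes or adjusted over the list alone (camera adjusted p = 0.39, and adjusted p = 0.652 with an estimated correlation). BIRC2 had a log2 fold change of 0.18 ± 0.061 and TNFRSF10B, a TRAIL receptor, of 0.15 ± 0.058. The death receptor list joins genes that promote cell death and genes that inhibit it, such as BIRC2. A directional test of it therefore cannot show a shift toward or away from death in either subset. Of 10 pro-apoptotic BCL2 family genes 0 were called (camera adjusted p = 0.829), with BBC3 at 0.14 ± 0.063 and BAX at 0.11 ± 0.060. The p53 target list was shifted higher, with 22 of 23 members above 0 but 0 called, at a median log2 fold change of 0.07. Its camera adjusted p was 0.000222, and with an estimated correlation the adjusted p = 0.109. FDXR was at 0.16 ± 0.060. TNFRSF10B, BBC3 and BAX are also members of the p53 target list, so these lists are not independent.

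Markers of other cell types and stress were read from their lists. The 5 tested dendritic cell markers were all above 0, with 0 called over all genes and 3 higher adjusted over the list alone. IL3RA, an interleukin-3 receptor chain, had a log2 fold change of 0.53 ± 0.103, and the transcription factor genes BATF3 and IRF8 had 0.36 ± 0.070 and 0.20 ± 0.061. The camera adjusted p was 1.53e-08, and the adjusted p = 0.109 with an estimated correlation. BATF3 averaged 79.9 CPM in CD4 siNS and 118 CPM in CD8 siNS, and IRF8 averaged 25.4 and 74.7 CPM. Both genes were thus well expressed in either subset, so their shift cannot be read as dendritic cell content. Of 37 interferon-stimulated genes 0 were called and 32 lay above 0, with STAT2 at 0.22 ± 0.064 and IFIH1 at 0.19 ± 0.083. That list's camera adjusted p was 0.00626, and with an estimated correlation the adjusted p = 0.82. Without the block 20 of the 37 lay above 0 (camera adjusted p = 0.649). In CD8 T cells, also without a block, all 37 lay above 0 at a median log2 fold change of 0.10, with 0 called. The camera adjusted p there was 0.0824, and 0.917 with an estimated correlation. Other lists were lower by camera. Of 6 monocyte and macrophage markers 5 lay below 0, with a median of -0.35, 0 called over all genes and 2 lower adjusted over the list alone (adjusted p = 0.00394; adjusted p = 0.299 with an estimated correlation). Of 7 gamma delta and innate-like T cell markers 6 lay below 0 and 0 were called (adjusted p = 0.0131, and 0.188 with an estimated correlation). Of 13 CD4 T cell markers CTLA4 was called lower over all genes and 1 adjusted over the list alone (adjusted p = 0.00344, and 0.128 with an estimated correlation). Of 16 cytotoxic granule genes 0 were called over all genes and 3 were lower adjusted over the list alone (adjusted p = 0.022, and 0.652 with an estimated correlation). Lower too by camera were glycolysis (adjusted p = 0.011) and T cell receptor signalling (0.012). So were cholesterol and fatty acid synthesis (0.0176) and the naive and central memory markers (0.0452). With an estimated correlation the adjusted p was 0.55, 0.198, 0.652 and 0.652 in turn, and 0 members were called over all genes. CD8A and CD8B were at 9.24 and 3.53 CPM in CD4 siFOXP3 replicate 3, and at no more than 1.22 and 1.19 CPM in the other CD4 siFOXP3 libraries. Without pair 3 the blocked fit called 4 genes higher and 7 lower, and these 11 were all among the 24.

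In CD8 T cells, compared without pairing because the replicate numbers did not pair these libraries, no gene passed the threshold after FOXP3 siRNA, FOXP3 included. This fit carries the full spread between libraries of a group. It missed FOXP3 itself at 2.48-fold lower, so changes of that size or smaller in CD8 T cells are not excluded. edgeR called 0 genes higher and 0 lower of 14942. At an unadjusted p under 0.05 it had 5 higher and 7 lower, fewer than chance alone gives on average. DESeq2 called 1 lower feature, which has no gene symbol. CD48 averaged 119 ± 39.8 CPM with siFOXP3 and 215 ± 51.1 CPM with siNS (SD, n = 5), a log2 fold change of -0.85 ± 0.248 (edgeR adjusted p = 1; exact permutation p = 0.0238). SPTY2D1 averaged 39.5 ± 6.63 and 58.9 ± 11.2 CPM, a log2 fold change of -0.58 ± 0.138 (edgeR adjusted p = 1; exact permutation p = 0.0159). CTLA4, which ranged widely between libraries (49.3 ± 43.2 CPM with siFOXP3 and 59.2 ± 49.7 CPM with siNS; SD, n = 5), was at -0.26 ± 0.743, and its sign turned when CD8 siNS replicate 1 was left out (0.30). In a fit with surrogate variables, added after the data were seen, SPTY2D1 alone was called (edgeR adjusted p = 0.00678).

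By list, 0 of 27 death receptor pathway genes were called in CD8 T cells (camera adjusted p = 0.673), with APAF1 at a log2 fold change of 0.17 ± 0.190. Of 14 SLAM receptors and adaptors 0 were called over all genes and 1, CD48, adjusted over the list alone; SLAMF8 was at -0.36 ± 0.389. The camera adjusted p of that list was 0.0236 in the lower direction, and with an estimated correlation the adjusted p = 0.666. Its median log2 fold change was -0.02 and 5 members lay above 0, while CD48 was at -0.85. All 55 ribosomal protein genes lay below 0 with a median of -0.07 and 0 called. Their camera adjusted p was 3.62e-06, and with an estimated correlation the adjusted p = 0.917. Glycolysis and the replication-dependent histone genes were also lower by camera (adjusted p = 0.0236 each), with adjusted p = 0.917 and 0.708 under an estimated correlation.

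The interaction asks whether FOXP3 siRNA acted differently in the subsets. edgeR called 0 genes of 14942, and DESeq2 called 1 feature without a gene symbol. At an unadjusted p under 0.05 edgeR had 6 genes above 0 and 5 below 0, fewer than chance alone gives on average. This fit leaves out the CD4 pairing and carries the full spread between libraries. A count of 0 therefore does not show that the subsets responded alike. The difference of the log2 fold changes, CD4 minus CD8, was -0.26 ± 0.438 for FOXP3, -0.17 ± 0.349 for CD48 and -0.12 ± 0.194 for SPTY2D1, each with an edgeR adjusted p of 1. No list passed (lowest camera adjusted p = 0.0565, ribosomal protein genes). With the replicate block over all 20 libraries, the dendritic cell markers passed (camera adjusted p = 0.0104). With an estimated correlation that adjusted p = 0.478.

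Under control siRNA, CD4 and CD8 T cells were separated by their lineage genes. CD4 averaged 396 ± 32.4 CPM in CD4 T cells and 7.42 ± 7.42 CPM in CD8 T cells (SD, n = 5; log2 fold change 5.74 ± 0.742, edgeR adjusted p = 8.97e-05). CD8A averaged 1.14 ± 0.329 and 591 ± 190 CPM (-9.01 ± 0.738, adjusted p = 3.93e-07), and CD8B 0.775 ± 0.183 and 190.0 ± 74.5 CPM (-7.93 ± 0.553). Higher in CD4 T cells were also PRG4 (7.52 ± 0.846), GNRH2 (5.46 ± 1.16) and CASR, the calcium-sensing receptor gene (4.88 ± 0.874). Higher in CD8 T cells were the NK receptor genes KLRK1 (-7.36 ± 0.481) and KLRC3 (-6.30 ± 0.705) and the adhesion molecule gene VCAM1 (-5.86 ± 0.534). Leaving out 1 library moved the fold of 4 of these genes by over 1.5 times, each still past the threshold: GNRH2 was at 3.91 ± 0.981 without CD4 siNS replicate 2 and KLRC3 at -7.18 ± 0.795 without CD4 siNS replicate 1. Without CD8 siNS replicate 1, PRG4 was at 8.71 ± 0.942 and CD4 at 6.49 ± 0.755. In all, 892 genes were higher in CD4 and 817 higher in CD8 by edgeR. Without CD4 siNS replicate 1 the counts were 1354 and 1585, and without CD4 siNS replicate 2 they were 604 and 406. Without CD4 siNS replicate 4 or 5, 448 or 515 genes were higher in CD8.

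Of 16 CD8 T cell markers, 15 were higher in CD8 and 0 higher in CD4, and 16 adjusted over the list alone, NKG7 among them (-3.12 ± 0.210). Of 13 CD4 T cell markers, 10 were higher in CD4, and 12 adjusted over the list alone, such as FBLN7 (4.58 ± 0.327), ZBTB7B, the regulator of the CD4 lineage (1.45 ± 0.150), and TNFRSF4 (2.63 ± 0.310). Both lists held with an estimated correlation (adjusted p = 5.65e-05 and 1.25e-06). Of 16 cytotoxic granule genes, 6 were higher in CD8 and 0 in CD4 (7 and 1 adjusted over the list alone). PRF1, perforin, was at -2.24 ± 0.409 and SERPINB9 at -1.24 ± 0.139. The camera adjusted p was 4.13e-08, and the adjusted p = 0.0938 with an estimated correlation. Of 14 NK cell markers, 8 were higher in CD8 over all genes and over the list alone, including KLRC1 (-5.49 ± 0.758), IL18RAP (-1.55 ± 0.385) and KLRD1 (-3.32 ± 0.830, and -4.55 ± 0.840 without CD4 siNS replicate 3). With an estimated correlation the adjusted p = 0.188. Of 17 naive and central memory markers, 6 were higher in CD4 and 2 in CD8 (8 and 2 adjusted over the list alone). CD28 was at 1.57 ± 0.0852, MAL at 2.23 ± 0.496 and BACH2 at -0.95 ± 0.210. The list's camera test pointed to CD4 (adjusted p = 0.0134; adjusted p = 0.584 with an estimated correlation) while its median was -0.04.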

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

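Of 154 groups of 5 libraries examined, 20 had 1 library far from the other 4 by Dixon's criterion, which chance gives in about 5 percent of groups. The test of a loss of regulatory T cells and the seed word tests with 3' UTR length removed and on words absent from FOXP3 mRNA were chosen after the result was seen; the tests of a shared stretch, of seed words and of CD8 T cell content were set before theirs.

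In CD4 replicate 1, several genes stood apart under both siRNAs. CTLA4 was at 598 CPM with siNS (others 74.8 to 161) and 449 CPM with siFOXP3 (others 50.7 to 101). IL17A was at 141 CPM with siNS (others 0.312 to 17.0) and 90.9 CPM with siFOXP3 (others 0.360 to 17.4). IL4 was at 4.40 CPM with siNS and 7.41 CPM with siFOXP3. In the siFOXP3 library of this number UBD was at 4.73 CPM, NEAT1 at 172 CPM and IL3RA at 4.85 CPM, each below the other 4. In its siNS library BBC3 was at 15.3 CPM, below the others, and HBD at 0.575 CPM, above them.

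STAT2 stood at 301 CPM in CD4 siNS replicate 4 and 302 CPM in CD4 siFOXP3 replicate 4, against no more than 98.8 and 125 CPM in the others. MALAT1 was at 156 CPM in CD4 siFOXP3 replicate 4. GNRH2 was at 7.24 CPM in CD4 siNS replicate 2. In CD4 siNS replicate 3 KLRD1 was at 6.98 CPM and ITGA2B at 1.71 CPM. CD28 was at 97.7 CPM in CD8 siNS replicate 4.

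CD8A was at 9.24 CPM and CD8B at 3.53 CPM in CD4 siFOXP3 replicate 3, each above the other 4 libraries. A few CD8 T cells in that library are a candidate explanation. Measured as a share of their level in CD8 siFOXP3 libraries, CD8A gave 1.47 percent and CD8B 1.53 percent. The other genes at least 32 times higher in CD8 and abundant there, KLRK1 and XCL2, gave a median share of 1.09 percent, close to that of CD8A. Only these 2 other genes could be used, and no biological explanation was tested.

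CD48 and SPTY2D1 were lower with FOXP3 siRNA in both subsets, and 1 siRNA was used, so an effect of the siRNA on other transcripts is a candidate explanation beside the loss of FOXP3. In the sense direction, the longest stretch that either transcript shares with FOXP3 mRNA was 11 bases for SPTY2D1 and 10 for CD48, at most the 8.7th percentile of transcripts of similar length, which argues against cross-targeting through a long shared stretch; in the antisense direction it was 12 and 11 bases, at the 42.8th and 34.8th percentiles. A match of the siRNA's short seed in the 3' UTR cannot be told apart. Of 1196 words of 7 bases from FOXP3 mRNA, 38 marked genes shifted lower in both subsets and 0 of these lay in both 3' UTRs. Words absent from FOXP3 mRNA passed too, though less often (130 of 14915 in both subsets at the same limits), and 99.3 percent of them lay below 0 in CD4. With 3' UTR length removed, passing FOXP3 words went from 1161 to 248 in CD4 and from 38 to 717 in CD8. Then 236 of them (19.73 percent) passed in both subsets, 3 of these in both 3' UTRs, against 7.74 percent of the words absent from FOXP3 mRNA; in CD4, 74.7 and 49.9 percent lay below 0. FOXP3 words thus passed more often than others, but others passed too and the outcome turned with the treatment of length, so the bound set beforehand decides nothing. A dependence of the 2 genes on FOXP3 stays open and was not tested.

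The Treg signature was lower in CD4 T cells in the paired fit. A loss of regulatory T cells from the siFOXP3 libraries could lower it, as could a dependence of its members on FOXP3. The median log2 fold change over its 29 members was -0.0844, while IL1R2 was at -0.87. Activated conventional T cells also express many members, such as CTLA4 and TNFRSF4, so a loss of these cells cannot be told apart from lower expression per cell. In CD4 T cells TNFRSF4 averaged 394.9 ± 142 CPM with siFOXP3 and 407.5 ± 155 CPM with siNS (SD, n = 5). The activation marker list did not pass in the paired fit (camera adjusted p = 0.848).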

How the results depend on the processing

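FOXP3 was lower in both subsets under each alternative run. In CD4 its log2 fold change passed the threshold with DESeq2 (-1.59), the replicate block within CD4 (-1.58) and surrogate variables (-1.59), and leaving out 1 library gave -1.67 to -1.46; in CD8 leaving out 1 library gave -1.61 to -1.10, never past the threshold. Without a block, DESeq2 called 2 genes lower in CD4, 1 feature lower in CD8 and 1 for the interaction, and surrogate variables 5 lower in CD4 and 1 in CD8; leaving out 1 library gave 0 throughout. The replicate block within CD4, added after the check of the numbers, called 9 higher and 15 lower.

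In CD8 the numbers did not pair the libraries: same-numbered siFOXP3 and siNS libraries correlated from -0.358 to 0.783, and 2 of 5 correlated best with their own number. The siFOXP3 libraries numbered 3, 4 and 5 each correlated best, and mutually, with a siNS library of another number (0.815, 0.817 and 0.728), a hint from the data and not the design; no pairs were formed from it, so the replicate block in CD8 joins libraries that deviate apart and is no check of a paired design there. Across subsets, under siNS, they ran from -0.21 to 0.129. The replicate block over all 20 libraries called 0 genes in CD8, CD4 and the interaction, and 1104 higher in CD4 and 1096 higher in CD8 between the subsets. With it, 2 lists passed in CD8 (adjusted p = 0.899 and 0.776 with an estimated correlation) and 1 for the interaction (0.478). It moved no count of genes by over 1.5 times.

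With the block in CD4, DESeq2 called 20 higher and 26 lower, no filter on low counts 26 and 30, and limma on log2(FPKM + 1) 2 and 7; it changes the measure, the test and the filter together, and the cause was not tested. Leaving out 1 pair gave 4 to 14 higher and 7 to 26 lower, without pairs 2, 3, 4 and 5 in turn 5, 4, 14 and 8 higher and 7, 7, 26 and 8 lower. DESeq2 kept 23 of the 24 genes and limma 9. Named genes in that fit kept their direction under each alternative, and 59 of 310 values lost the threshold. The 310 values cover 31 genes, and some of these, such as IL4 and BAX, were not past the threshold to begin with. The share lost among the called genes is therefore larger.

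Between CD4 and CD8, DESeq2 called 1356 genes higher in CD4, and a fit of only these groups, with fewer libraries, 556 and 393. Leaving out 1 library gave 604 to 1354 higher in CD4 and 406 to 1585 higher in CD8. CTLA4 in CD8 ran from -0.90 to 0.30 when 1 library was left out, reversed without CD8 siNS replicate 1. Of the fixed lists, 4 passed in CD4, 4 in CD8 and 12 between subsets; with an estimated correlation 0, 0 and 2 did. The 4 in CD4 were the Treg signature, the p53 targets, the SLAM receptors and adaptors, and the dendritic cell markers. The block within CD4 gave 15, and 0 with an estimated correlation. Where no construction is named, the cause was not tested. The lowest total, 22602220 counts, limits mainly genes near 1 CPM.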

Other observations

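Between CD4 and CD8 T cells under siNS, death receptor genes went both ways: 5 of 27 were higher in CD4 and 1 in CD8 (7 and 4 adjusted over the list alone). TNFRSF25, which encodes death receptor 3, was higher in CD4 (log2 fold change 1.16 ± 0.169, edgeR adjusted p = 0.00026), as was the deubiquitinase gene CYLD (0.74 ± 0.191). Of 14 SLAM receptors and adaptors, 4 were higher in CD8 and 1 in CD4, with SLAMF7 at -2.52 ± 0.300, CD244 at -2.10 ± 0.396 and SLAMF6 at -0.68 ± 0.140; the list's adjusted p = 0.215 with an estimated correlation. Of 33 T cell receptor signalling genes, 6 were higher in CD4 and 1 in CD8, with CD5 at 1.07 ± 0.156 and CD6 at 0.78 ± 0.0956; adjusted p = 0.488 with an estimated correlation. Of 5 platelet and erythroid markers, 4 were higher in CD8, with HBA1 at 1.65 ± 1.58 CPM, HBD at 12.5 ± 15.4 CPM and ITGA2B at 10.7 ± 11.3 CPM in CD8 siNS (SD, n = 5); adjusted p = 0.451 with an estimated correlation. Without CD8 siNS replicate 5 the log2 fold change went from -6.357 to -5.624 for HBA1 and from -5.715 to -4.765 for HBD. That of ITGA2B went from -3.417 to -2.754, and all of them stayed past the threshold.

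The test of the CD4 genes in CD8 was chosen after values of some of these genes in CD8 had been seen; the splits below were planned. The genes called in the paired CD4 fit may also shift in CD8 T cells. Of the 22 tested there without FOXP3, 20 had the same sign in CD8, and as a signed set they gave a fry p of 0.108 by limma. Without SPTY2D1 and CD48, 18 of 20 had the same sign and the fry p was 0.392. The genes are correlated, so the count of signs is no test, and the shift in CD8 stays open.

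Chance is an unlikely source of the count between CD4 and CD8. Of 100 splits of the siNS libraries, 1, the real one, gave 1709 or more genes, and the highest of the others gave 1069. Total counts also differed without overlap, from 22602220 to 26510383 in CD4 siNS and from 29290655 to 40769229 in CD8 siNS. The splits cannot tell the subset from such other differences between these libraries. For the unblocked counts of 0 in CD4, in CD8 and for the interaction, any split gives as many, so the splits say nothing about chance. The highest of the other splits gave 671, 684 and 699 genes, which points to a structure of the libraries other than the siRNA. In the paired CD4 fit, the 16 splits that part all 5 pairs are too few for a share under 0.05. The real split gave 24 genes, 1 split of the 16. The highest other gave 13, but it exchanges the siRNA labels only within pair 4 and so keeps most of the real labels. The remaining splits gave 2 or fewer.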
